A study of Homo sapiens with 15 samples.

How the data were processed

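Total RNA of OCI-AML5 cells was sequenced in 15 libraries, 3 for each of 5 groups. Per the labels' protocols, cells grew in Alpha MEM with 20% serum and 10 ng/mL GM-CSF, were exposed to 1000 nM OTX015 or 1000 nM ARV-825 for 4 h or transduced with an shRNA for 72 h, RNA was isolated with an Ambion kit and treated with DNase, and libraries were made with an Illumina kit. Neither poly(A) selection nor strand is stated in the labels, so reads of overlapping antisense genes cannot be told apart. Groups were taken from the treatment labels. The titles of the RUNX1 shRNA group name Runx3, and the treatment label was followed. The series calls the samples biologic triplicates and names no shared day or batch, and p-values measure the spread between these libraries, part of which can be technical.

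The authors deposited 1 table of the 9 drug libraries and 1 of the 6 shRNA libraries, each with 19620 entries for protein-coding genes. Values were read as FPKM (fragments per kilobase of transcript, scaled to library size), quantile normalized by the authors within each table, because Cufflinks 2.0 is listed per the submitters' processing notes and the values are never negative, are not whole, differ in sum and recur between libraries. Of the values above 0 in a library, 68.9% to 75.3% recurred exactly in another library of its table, against 0.0197% to 0.0466% across the tables. At equal ranks at most 6.16% were equal, so normalization is taken to have run over more genes than the tables list, which the sources do not state. The table names state coding genes and carry an abbreviation read as quantile normalization, and no unit. The column headers name no unit. TopHat2 2.0 and the build hg19 are also listed per the submitters' processing notes. The gene annotation used is not given in the sources used here. The values listed therefore keep differences in distribution between libraries, yet a change in total RNA per cell cannot be seen in them. Depth per library is unknown, and no counting interval can be given. The sum of FPKM ran from 554570 to 656995. The median was 2.15 to 2.2 in control, 2.06 to 2.1 with OTX015 and 1.8 to 1.92 with ARV-825, and 2.57 to 2.58 with non-targeting and 2.52 to 2.56 with RUNX1 shRNA. ARV-825 replicate 1 lists 6 mitochondrially encoded genes at 0, which are abundant in the other libraries, so a value of 0 can be a failed estimate.

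Gene IDs were matched to symbols of GENCODE release 29, with 19313 matched. That annotation is of another build than hg19, and it served for symbols, 3' UTR sequences and gene spans, with no coordinates reported. Left out were 16 pseudoautosomal copies on the Y chromosome, and 28 symbols that a spreadsheet had turned into dates were restored from their IDs. Pearson correlations across genes were 0.978 to 0.997 within groups and 0.905 to 0.974 between groups in the drug table, and 0.994 to 0.997 and 0.986 to 0.991 in the shRNA table. Among tested genes (mean of at least 1 FPKM), no pair of libraries had more than 60 with exactly equal values, so no library was counted as a copy of another.

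Values were analysed as log2(FPKM + 1), a scale that understates the change of genes near or below 1 FPKM, and fold changes are on that scale. Genes with a mean of at least 1 FPKM over the libraries of a fit were tested with limma 3.58.1 (lmFit and eBayes with a mean-variance trend, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of adjusted p = 0.05. The 9 drug libraries shared 1 fit with the contrasts ARV-825 against control, OTX015 against control and ARV-825 against OTX015. The 6 shRNA libraries had a fit of their own, because the tables were normalized separately, and no test crosses the tables except by sets of called genes. Intervals are 95% intervals of limma, and log2 changes have their standard error.

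Groups, designs, the alternative settings, the rule for named genes and 31 gene lists were fixed before the data were examined. Of the lists, 26 were tested: BET and P-TEFb genes, histone genes, MYC-associated genes, ribosomal proteins, haematopoietic transcription factors, reported RUNX1 targets, monocyte and macrophage genes, neutrophil granule genes, stem and progenitor genes, G1/S genes, G2/M genes, G1 cyclins and their kinases and inhibitors, anti-apoptotic and pro-apoptotic genes, p53 targets, NF-kB and cytokine genes, interferon-stimulated genes, unfolded protein and integrated stress response genes, heat shock genes, immediate early genes, GM-CSF and STAT5 response genes, cholesterol synthesis genes, glycolysis genes, cereblon ligase genes and neosubstrates, proteasome subunits and mitochondrially encoded genes. Markers of 5 other cell types were checked for their level. Some genes stand in more than 1 list, for example CDKN1A, GATA2 and NFE2. Lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. With an estimated correlation, camera takes its degrees of freedom from the few libraries in place of the many genes. That alone raises p, so a call lost at this setting is no measure of correlation by itself. Fry asks whether the genes of a set move on balance in a single direction, and makes no comparison with other genes.

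Named genes were, per comparison, the 6 with the largest rise and the 6 with the largest fall among called genes with groups fully apart, leaving out XIST and genes of the Y chromosome, then 20 key genes whatever their result, and up to 3 members per described list with the largest absolute change among those called. For genes shared by RUNX1 shRNA and ARV-825, the 5 with the largest rise and the 5 with the largest fall in common were taken. Some genes that this rule selects are not reported here. Genes named for opposite changes with the drugs, and genes named for a 7-mer in their 3' UTR, were chosen after their values were seen.

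The fit was tested on simulated data with 200 changed genes in 10 simulations for each comparison. Changes of 1 on the log2 scale were recovered in 97.2% of genes for ARV-825 against control, 95.2% for OTX015 against control, 97.8% for ARV-825 against OTX015 and 97.2% for RUNX1 shRNA, and changes of 0.25 in 29.6%, 29.6%, 31.2% and 41.2%. False calls were 6.04%, 4.73%, 5.2% and 4.22% of calls. A list shifted by 0.5, that of ribosomal proteins, was called in 10 of 10 simulations in each comparison. Simulated genes were drawn independently, while the estimated correlation of this list was 0.555 in the drug and 0.279 in the shRNA libraries. The rates therefore need not hold for correlated genes, or where far more than 200 genes change. The effects of shared control libraries were simulated with 100 draws of unchanged groups.

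For each 7-mer in annotated 3' UTRs of at least 30 bases that occurred in at least 50 genes, log2 changes limited to an absolute value of 3 were regressed on its presence, with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. Alternative settings chosen then were pseudocounts of 0.1 and 5, no filter on low values, a mean of at least 5 FPKM, rescaling of each library by the median ratio to the geometric mean, limma without the trend, the replicate number as a block, an added threshold of 1 on the absolute log2 change, only the libraries of the groups compared, an estimated correlation or fry for lists, sets limited to an absolute log2 change of at least 1, and leaving out each library in turn. Chosen after the data were seen were quantile normalization repeated without mitochondrially encoded genes, removal of genes holding the 7-mer, and, for the RUNX1 shRNA sets, fry and 2-fold sets without histone genes. The set tests of genes called with RUNX1 shRNA were adjusted over 4 tests at each setting. The alternatives of these sets were at first compared by unadjusted values and were put on this adjusted scale after the values were seen.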

Results

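RNA sequencing of total RNA measured gene expression in OCI-AML5, an established acute myeloid leukaemia line grown with the cytokine GM-CSF. The 15 libraries formed 5 groups of 3. In the drug experiment, cells were left untreated or exposed for 4 h to 1000 nM OTX015 or 1000 nM ARV-825. OTX015 is an inhibitor of BET bromodomain proteins, which bind acetylated histones and recruit the transcription elongation machinery. ARV-825 is OTX015 joined by a linker to a ligand of cereblon, an E3 ubiquitin ligase subunit, so that BET proteins are tagged for degradation. In the shRNA experiment, cells carried a non-targeting shRNA or an shRNA against RUNX1 for 72 h. RUNX1 is a transcription factor of blood cell development, and the series is about RUNX1 knockdown and BET protein degradation in leukaemia cells with mutant RUNX1. Values were read as FPKM, a unit that the tables do not state, and the drug libraries and the shRNA libraries had been normalized separately. The sum of FPKM per library ran from 554570 to 656995, and 10496 to 10927 genes per library reached 1 FPKM. In the drug libraries the median FPKM was 2.15 to 2.2 in control, 2.06 to 2.1 with OTX015 and 1.8 to 1.92 with ARV-825, with 10738 to 10780, 10638 to 10703 and 10496 to 10588 genes at 1 FPKM or more. The number of reads behind each library is unknown.

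Markers of other cell types were mostly below 1 FPKM. In the drug libraries a mean of 1 FPKM was reached by 2 of 15 erythroid, 3 of 14 megakaryocyte and platelet, 1 of 14 B cell, 4 of 16 T and NK cell, and 1 of 17 epithelial and fibroblast markers. The highest were NKG7, a granule protein of killer cells, at 37.4 FPKM, the transferrin receptor TFRC at 32.6 FPKM, the synaptic and platelet protein NRGN at 31.5 FPKM, the B cell receptor subunit CD79A at 3.99 FPKM and the matrix protein FBN1 at 1.21 FPKM. In the shRNA libraries the same lists had 2, 2, 1, 3 and 0 members at that level.

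The first comparison asked how ARV-825 changed expression within 4 h. MYC, a transcription factor that drives growth, fell from 288 ± 6.99 FPKM in control to 23.0 ± 1.47 FPKM (mean ± SD, n = 3 libraries per group). MYB, which sustains immature blood cells, fell from 180.5 ± 2.88 to 26.1 ± 0.538 FPKM, and the myeloid regulator SPI1 from 208 ± 15.1 to 59.9 ± 1.96 FPKM. RUNX1 itself fell from 61.4 ± 2.09 to 36.2 ± 2.39 FPKM. HEXIM1, an inhibitor of P-TEFb and a common marker of BET inhibition, rose from 11.3 ± 0.879 to 49.7 ± 2.2 FPKM. Limma with Benjamini-Hochberg adjustment called 8025 of 10819 tested genes (74.2%), of which 3869 rose (48.2%, or 52.5% of 8088 after median-ratio rescaling) and 4156 fell, with 476 up and 883 down by at least 2-fold. The median absolute log2 change of the called genes was 0.52. All 3 libraries of a group lay above or below all 3 of the other in 76.2% of tested genes, against 10% by chance, and this held for each gene said in the text to have risen or fallen.

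The log2 changes of MYC, MYB and SPI1 were -3.59 ± 0.048 (SE, adjusted p = 5.55e-12), -2.75 ± 0.043 (adjusted p = 2.23e-11) and -1.78 ± 0.06 (adjusted p = 2.03e-09). RUNX1 changed by -0.75 ± 0.068 (adjusted p = 2.38e-06), its family member RUNX3 by -1.11 ± 0.088 (adjusted p = 7.94e-07), and CBFB, the partner of both, by -0.51 ± 0.05 (adjusted p = 3.95e-06). CEBPA, a granulocyte regulator, fell by 0.94 on the log2 scale (adjusted p = 1.41e-06). Of the survival genes, BCL2 fell from 16.6 ± 0.556 to 3.89 ± 0.267 FPKM (-1.85) and BCL2L1, which encodes BCL-xL, from 17.5 ± 0.814 to 5.26 ± 0.533 FPKM (-1.56), while MCL1 rose from 65.3 ± 1.63 to 113.5 ± 6.85 FPKM (0.79). The cell cycle inhibitors CDKN1A (p21) and CDKN1B (p27) rose by 1.90 ± 0.078 and 0.69 ± 0.058, the pro-apoptotic BCL2L11 (BIM) rose by 0.29 ± 0.065, and the G1 kinase CDK6 fell by 0.69 ± 0.184 on the log2 scale. SERPINI1, a protease inhibitor gene also used as a marker of BET inhibition, rose from 0.47 ± 0.0722 to 8.91 ± 0.907 FPKM. Among the drug targets, BRD2 rose from 93.0 ± 7.1 to 225 ± 20.8 FPKM. The change of BRD3 was 0.16 (95% interval -0.006 to 0.331, adjusted p = 0.0739) and that of CRBN, which encodes cereblon, was -0.11 (adjusted p = 0.224). BRD3 passed the threshold without ARV-825 replicate 3 (0.25, adjusted p = 0.00361) and after median-ratio rescaling (adjusted p = 0.0473).

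**Figure D1:**
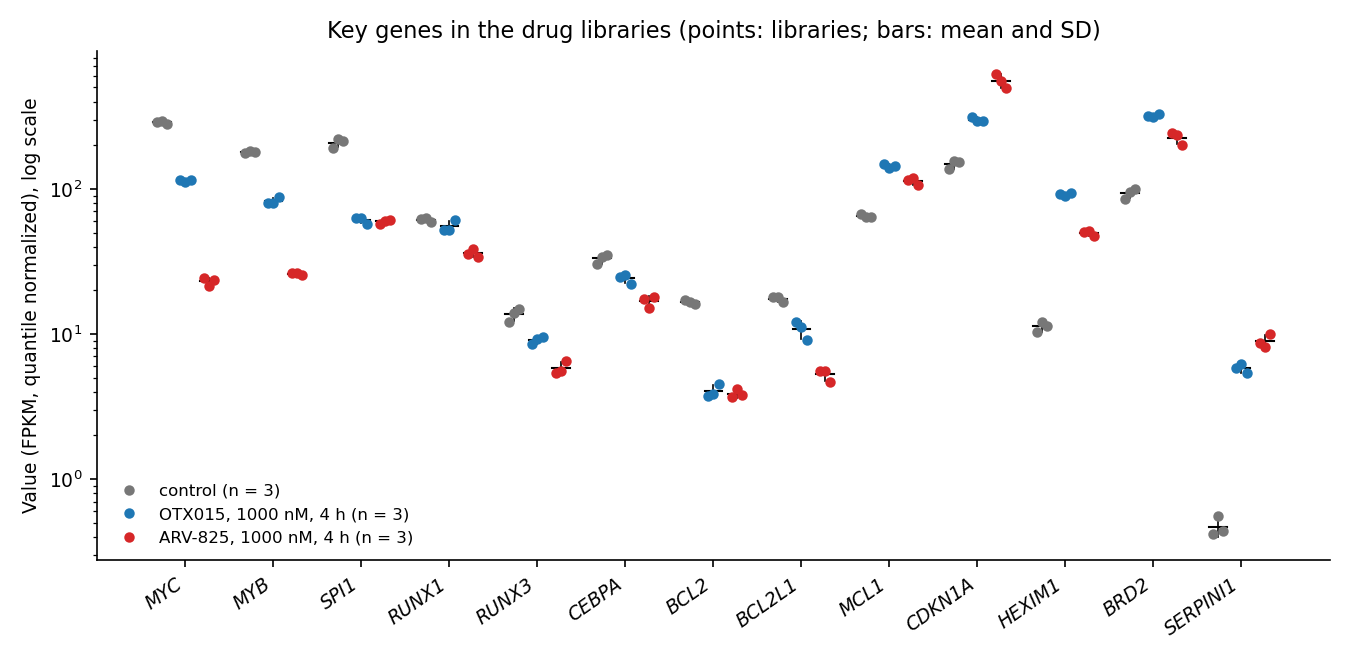
FPKM of 13 genes on a log axis in control, OTX015 and ARV-825 libraries, with points for the 3 libraries of a group and bars for the mean and SD. MYC stood at 288, 113 and 23.0 FPKM in the 3 groups, SPI1 at 208, 61.4 and 59.9 FPKM, and HEXIM1 at 11.3, 92.0 and 49.7 FPKM.

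The largest rises after ARV-825 were in replication-dependent histone genes, which package newly made DNA. HIST1H2AC rose from 3.45 ± 0.17 to 109 ± 2.92 FPKM (log2 change 4.63, adjusted p = 2.65e-13), followed by HIST2H4A (4.10), HIST2H4B (3.90), HIST2H3C (3.85), HIST2H3A (3.85) and HIST1H2BH (3.55). The paired copies HIST2H4A and HIST2H4B, and HIST2H3A and HIST2H3C, are near-identical and share reads, so their separate values are uncertain. Among other genes that fell far, the monocyte chemokine receptor CCR2 fell from 33.2 ± 1.64 to 0.493 ± 0.274 FPKM (-4.53, adjusted p = 3.72e-10), CXorf21 from 85.4 ± 4.73 to 5.97 ± 0.781 FPKM, ANKRD55 from 18.6 ± 0.737 to 0.627 ± 0.0718 FPKM and the platelet-activating factor receptor PTAFR from 33.2 ± 0.276 to 2.09 ± 0.242 FPKM.

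Of 26 gene lists written before the data were examined, 5 moved as sets in camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01. Replication-dependent histone genes rose, with 30 of 35 up and 0 down, also adjusted over the list alone (median log2 change 1.94, adjusted p = 3.72e-08, and adjusted p = 0.704 with an estimated correlation). MYC-associated nucleolar and biosynthetic genes fell, 35 of 40 down and 2 up, or 36 and 2 adjusted over the list alone (median -0.80, adjusted p = 3.72e-08, and adjusted p = 0.162 with an estimated correlation). Among them were the ribosome assembly factors NOP16 (-2.05) and WDR43 (-1.82) and the RNA polymerase I subunit POLR1B (-2.01). Haematopoietic transcription factors fell, 26 of 28 down and 1 up over all genes and adjusted over the list alone (median -1.15, adjusted p = 3.72e-08, and adjusted p = 0.0758 with an estimated correlation). NFE2, an erythroid and platelet regulator, fell from 38.6 ± 1.12 to 3.81 ± 0.183 FPKM, and the repressor GFI1 changed by -1.87. Targets of p53 rose, 18 of 25 up and 4 down, the same adjusted over the list alone (median 0.63, adjusted p = 0.000345, and adjusted p = 0.311 with an estimated correlation). They were led by the p53 ligase gene MDM2, from 74.6 ± 5.54 to 291 ± 52.1 FPKM, CDKN1A, and the stress gene TP53INP1 (1.72). Cholesterol synthesis genes rose, 19 of 24 up and 1 down, the same adjusted over the list alone (median 0.43, adjusted p = 0.000232, and adjusted p = 0.199 with an estimated correlation). Among them were the sterol reductase TM7SF2 (1.64), the sterol carrier STARD4 (1.20) and the isoprenoid enzyme IDI1 (1.18). None of the 5 calls held with an estimated correlation. Standard errors of the log2 changes named for ARV-825 ran from 0.041 to 0.237.

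The other 21 lists were not called as sets after ARV-825 (adjusted p = 0.102 to 0.986), though many of their members changed in opposite directions. Immediate early genes had 16 up and 7 down of 24 (median 0.41, adjusted p = 0.102, and 0.00995 at a mean of at least 5 FPKM). The transcription factor KLF2 rose from 6.06 ± 0.898 to 63.6 ± 6.05 FPKM and the mRNA decay factor ZFP36 rose by 2.14. Heat shock genes had 3 up and 10 down of 19 (median -0.25), including the chaperone genes CHORDC1 (-1.18) and HSPA8 (-0.89). NF-kB and cytokine genes had 7 up and 8 down of 20 (median -0.16). The chemokine gene CCL2 fell from 83.9 ± 6.86 to 8.25 ± 1.09 FPKM, and CXCL8 changed by -2.60. Monocyte and macrophage genes had 8 up and 12 down of 23 (median -0.18; 9 and 12 adjusted over the list alone), with CD180, a B cell and monocyte receptor, at -2.93. Neutrophil granule genes had 5 up and 3 down of 10 (median 0.22), including the granule protein AZU1 (0.97) and the complement factor CFD (0.70). Stem and progenitor genes had 0 up and 4 down of 7 (median -0.22), including the transcription factors GATA2 (-1.85) and SOX4 (-1.15).

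Among growth and death lists, G1/S genes had 12 up and 14 down of 30 (median 0.04, mean -0.01), with the activator E2F2 at -1.10 and thymidine kinase TK1 at 0.90, and G2/M genes had 11 up and 11 down of 30 (median -0.01; 11 and 12 adjusted over the list alone), with the mitotic regulator FOXM1 at -1.01. G1 cyclins, kinases and inhibitors had 7 up and 5 down of 14 (median 0.12), anti-apoptotic genes 2 up and 4 down of 7 (median -0.52), and pro-apoptotic genes 7 up and 7 down of 17 (median -0.12). PMAIP1 (NOXA) rose from 10.9 ± 1.39 to 22.65 ± 0.917 FPKM, and the death receptor FAS changed by -0.94. BET and P-TEFb genes had 13 up and 8 down of 24 (median 0.21; 14 and 8 adjusted over the list alone), including the elongation factor ELL2 (1.39). Interferon-stimulated genes had 8 up and 7 down of 19 (median -0.06, mean 0.03). The interferon regulator IRF7 rose from 5.14 ± 0.395 to 47.0 ± 2.29 FPKM, and the pro-apoptotic XAF1 changed by -2.30. Unfolded protein and integrated stress response genes had 11 up and 8 down of 25 (median -0.06, test direction up), including the glutathione-degrading CHAC1 (-2.64) and the kinase-like regulator TRIB3 (-2.49). GM-CSF and STAT5 response genes had 7 up and 10 down of 22 (median -0.23), including the cytokine signal inhibitor SOCS3 (2.12) and the kinase PIM1 (-1.60). Cereblon ligase genes and neosubstrates had 2 up and 4 down of 9 (median -0.11; 3 and 4 adjusted over the list alone), including the zinc finger gene ZFP91, from 31.8 ± 1.09 to 14.99 ± 0.42 FPKM. Reported RUNX1 target genes had 8 up and 8 down of 18 (median -0.06), glycolysis genes 8 up and 6 down of 22 (median 0.04). Proteasome subunits had 5 up and 11 down of 28 (median -0.04), ribosomal proteins had 3 up and 0 down of 44 (median 0.08; 0 and 0 adjusted over the list alone), and mitochondrially encoded genes 0 up and 0 down of 13. The median of the mitochondrial list was 0.09 and its mean -2.03, because 6 of its genes were listed at 0 in ARV-825 replicate 1.

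OTX015, the parent BET inhibitor at the same dose and time, also lowered MYC and raised HEXIM1. MYC fell from 288 ± 6.99 to 113 ± 1.87 FPKM (log2 change -1.34 ± 0.048, n = 3 libraries per group, adjusted p = 4.29e-09), MYB from 180.5 ± 2.88 to 82.6 ± 4.22 FPKM (-1.12 ± 0.043) and SPI1 from 208 ± 15.1 to 61.4 ± 3.54 FPKM (-1.75 ± 0.06, adjusted p = 3.57e-09). HEXIM1 rose from 11.3 ± 0.879 to 92.0 ± 1.77 FPKM (2.92 ± 0.056, adjusted p = 1.13e-10), SERPINI1 to 5.82 ± 0.431 FPKM and BRD2 to 319.5 ± 8.68 FPKM. BCL2 fell from 16.6 ± 0.556 to 4.06 ± 0.42 FPKM. Limma called 7528 of 10819 genes (69.6%), of which 3901 rose and 3627 fell, with 325 up and 537 down by at least 2-fold. The groups were fully apart in 75.3% of genes, against 10% by chance, and the median absolute log2 change of called genes was 0.47.

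The change of RUNX1 after OTX015 was -0.15 (95% interval -0.304 to -0.002, adjusted p = 0.0668), and it passed the threshold without OTX015 replicate 3 (-0.23, adjusted p = 0.00566). RUNX3 fell by 0.54 ± 0.088 on the log2 scale (adjusted p = 0.000269), CBFB by 0.27 ± 0.05, CEBPA by 0.44 ± 0.08, BCL2L1 by 0.66 ± 0.097 and CDK6 by 0.90 ± 0.184. MCL1 rose by 1.13 ± 0.048, CDKN1A by 1.02 ± 0.078, CDKN1B by 0.49 ± 0.058 and BCL2L11 by 0.67 ± 0.065. The changes of BRD3 and CRBN were 0.10 (adjusted p = 0.253) and 0.12 (adjusted p = 0.194). Histone genes again led the rises, with HIST1H2AC at 165 ± 3.58 FPKM (5.23, adjusted p = 7.37e-14), HIST2H4A at 94.2 ± 11.4 FPKM and HIST2H4B at 51.2 ± 4.3 FPKM. HIST2H2AA3 stood at 278 ± 8.49 FPKM from 17.5 ± 2.49 in control, and HIST2H2AA4 at 274 ± 9.33 FPKM from 17.6 ± 2.74. The gene listed as RP1-34B20.21 rose from 1.45 ± 0.0887 to 42.3 ± 6.52 FPKM. HIST2H2AA3 and HIST2H2AA4 are near-identical copies, like the HIST2H4 pair, and their separate values are uncertain. CCR2 fell to 2.16 ± 0.0801 FPKM (-3.43) and the galectin LGALS12 from 36.3 ± 1.02 to 2.65 ± 0.0673 FPKM. TIFAB, an inhibitor of TRAF6 signalling, fell from 9.94 ± 0.181 to 0.197 ± 0.044 FPKM, ANKRD55 to 1.15 ± 0.216 FPKM, the interleukin-1 receptor antagonist IL1RN from 79.2 ± 4.71 to 8.59 ± 1.23 FPKM, and C1orf186 from 42.6 ± 3.25 to 4.21 ± 0.459 FPKM.

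Camera called 6 lists after OTX015. Histone genes rose, 29 of 35 up and 0 down, the same adjusted over the list alone (median 1.89, adjusted p = 6.17e-08, and adjusted p = 0.614 with an estimated correlation). MYC-associated genes fell, 38 of 40 down and 0 up, the same adjusted over the list alone (median -0.84, adjusted p = 3.84e-12, and adjusted p = 0.0573 with an estimated correlation). They included NOP16 (-1.89), the folate carrier SLC19A1 (-1.54) and the ribosome factor MRTO4 (-1.42). Haematopoietic transcription factors fell, 20 of 28 down and 2 up, the same adjusted over the list alone (median -0.50, adjusted p = 6.86e-05, and adjusted p = 0.105 with an estimated correlation). ERG, a stem cell factor, fell from 6.215 ± 0.28 to 0.749 ± 0.0621 FPKM, the granulocyte factor CEBPE from 16.1 ± 1.15 to 3.32 ± 0.333 FPKM, and TAL1 changed by -1.83. Monocyte and macrophage genes fell, 15 of 23 down and 0 up, the same adjusted over the list alone (median -0.70, adjusted p = 1.28e-05). This call alone of the 6 held with an estimated correlation (adjusted p = 0.0467). It included CCR2, the macrophage growth factor receptor CSF1R, from 41.1 ± 0.98 to 8.26 ± 0.214 FPKM, and the Fc receptor FCGR1A, from 53.6 ± 4.05 to 11.7 ± 1.14 FPKM. Stem and progenitor genes fell, 6 of 7 down and 0 up, the same adjusted over the list alone (median -0.46, adjusted p = 0.0291, and adjusted p = 0.483 with an estimated correlation). Members were GATA2 (-1.41), NPR3 (-1.62) and the surface marker CD34 (-0.83). This call was lost without a filter on low values (adjusted p = 0.0544). Immediate early genes rose, 19 of 24 up and 5 down, the same adjusted over the list alone (median 0.89, adjusted p = 0.000425, and adjusted p = 0.142 with an estimated correlation). KLF2 stood at 72.35 ± 6.29 FPKM, ZFP36 rose from 28.4 ± 2.21 to 242 ± 9.03 FPKM, and the AP-1 subunit FOSL1 changed by -1.74.

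The remaining 20 lists were not called after OTX015 (adjusted p = 0.0617 to 0.886). Nearest to the threshold were p53 targets, 17 up and 7 down of 25 (median 0.29, adjusted p = 0.0617), with TP53INP1 at 1.84 and the growth inhibitor BTG2 at 1.60. BET and P-TEFb genes had 14 up and 5 down of 24, or 14 and 7 adjusted over the list alone (median 0.40, adjusted p = 0.0617). Both passed without OTX015 replicate 2 (adjusted p = 0.0498 and 0.0391) and without a filter on low values (0.0215 and 0.0345), and p53 targets also at a mean of at least 5 FPKM (0.0394). Members of uncalled lists that changed included IRF7 (3.01), CCL2 (-2.58), SOCS3 (1.55), the sterol gene TM7SF2 (2.14), the eIF2 phosphatase subunit PPP1R15A (1.60), HSPA6 (-1.61), the ribonucleotide reductase subunit RRM2 (0.93), CCND1 (-1.68) and the zinc finger gene ZNF692, from 31.5 ± 0.657 to 10.0 ± 1.32 FPKM. Standard errors of the log2 changes named for OTX015 ran from 0.043 to 0.184. Medians of the interferon and GM-CSF response lists were -0.07 and -0.02, and the test direction was down for the former and up for the latter.

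**Figure D2:**
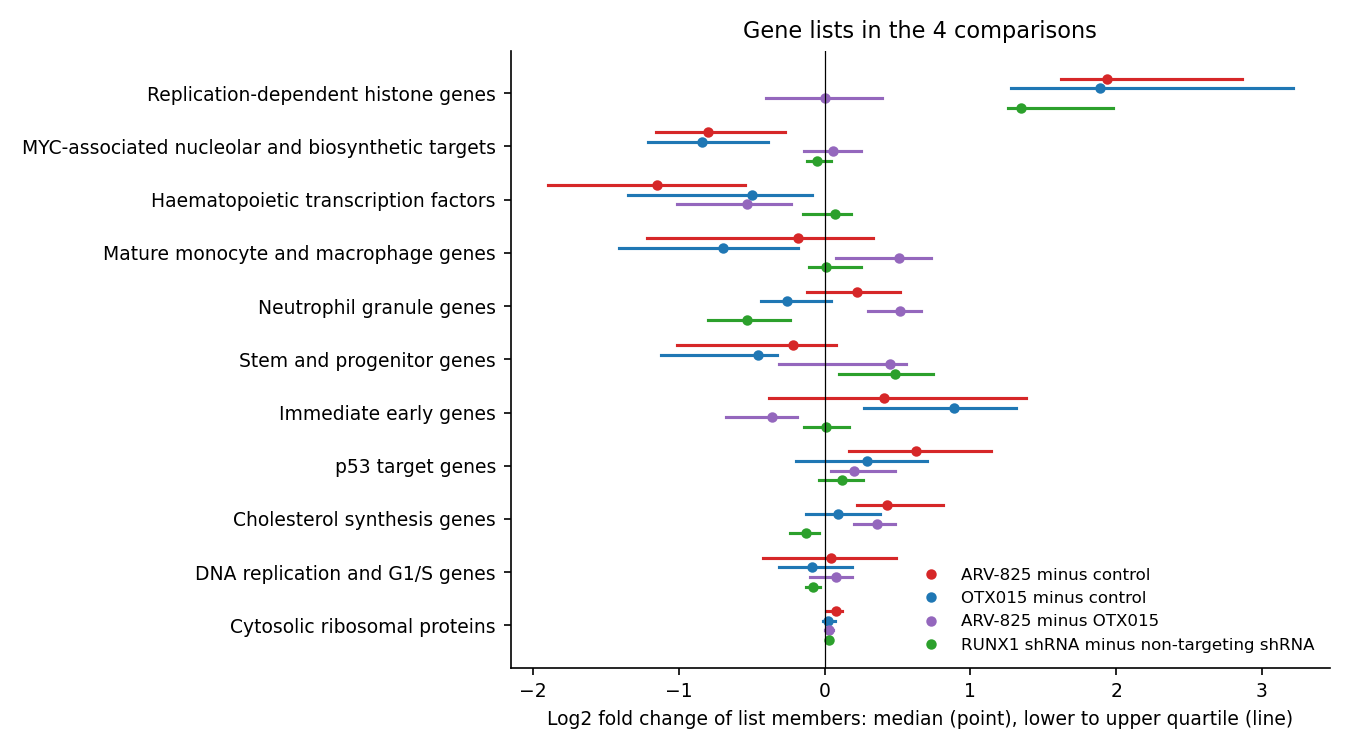
Median log2 change (points) and quartiles (bars) of 11 gene lists in the 4 comparisons. The histone list had medians of 1.94 with ARV-825, 1.89 with OTX015 and 1.35 with RUNX1 shRNA, and the MYC-associated list had medians of -0.80 and -0.84 with the drugs.

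ARV-825 and OTX015 were then compared directly at equal dose and time. This contrast is between whole compounds, so it cannot separate BET protein degradation from other differences between them. With ARV-825, MYC was lower by -2.25 ± 0.048 (adjusted p = 1.47e-09) and MYB by -1.63 ± 0.043 (adjusted p = 4.69e-09) than with OTX015 (n = 3 libraries per group). RUNX1 was lower by -0.59 ± 0.068 (adjusted p = 4.56e-05), RUNX3 by -0.58 ± 0.088, CBFB by -0.24 ± 0.05, CEBPA by -0.50 ± 0.08 and BCL2L1 by -0.91 ± 0.097. CDKN1A was higher with ARV-825 by 0.89 ± 0.078 and SERPINI1 by 0.54 ± 0.087. HEXIM1 (-0.88 ± 0.056), BRD2 (-0.51 ± 0.072), MCL1 (-0.34 ± 0.048) and BCL2L11 (-0.38 ± 0.065) were lower with ARV-825 than with OTX015. No difference was detected for SPI1 (-0.03, 95% interval -0.167 to 0.099, adjusted p = 0.644), BCL2 (-0.05, -0.217 to 0.122, adjusted p = 0.617), BRD3 (0.06, -0.107 to 0.229, adjusted p = 0.516) or CDK6 (0.21, -0.201 to 0.613, adjusted p = 0.359). CDKN1B was higher by 0.20 with ARV-825 (adjusted p = 0.012). CRBN was lower by -0.23 (adjusted p = 0.0272), a call lost without a filter on low values (adjusted p = 0.0523), after median-ratio rescaling (0.0693), and without OTX015 replicate 1 (0.0936), OTX015 replicate 3 (0.0505) or ARV-825 replicate 2 (0.086).

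Between the compounds 6282 of 10819 genes differed (58.1%), 2672 higher and 3610 lower with ARV-825, and 91 higher and 114 lower by at least 2-fold. The excess of lower genes depended on the scaling, as the share of higher genes was 42.5% in the deposited values and 50.8% of 6334 after median-ratio rescaling. The median absolute log2 difference of called genes was 0.38. The groups were fully apart in 62% of genes, against 10% by chance. The largest differences up were PLEKHA6, at 6.44 ± 3.1 FPKM with ARV-825 and 0.0647 ± 0.0743 with OTX015, KIAA1683, at 10.0 ± 0.986 and 0.918 ± 0.156 FPKM. Next were the carboxypeptidase CPM, at 29.6 ± 9.44 and 4.48 ± 0.385 FPKM, LSMEM1, at 9.04 ± 0.984 and 1.20 ± 0.306 FPKM, and the actin-binding AVIL, at 7.43 ± 0.978 and 1.05 ± 0.028 FPKM. GAGE12B, a cancer-testis antigen of a family of near-identical copies whose value is therefore uncertain, was listed at 0 in all 3 OTX015 libraries and at 5.56, 3.02 and 5.80 FPKM with ARV-825. Lower with ARV-825, after MYC, were the activation marker CD69, at 0.755 ± 0.267 against 6.18 ± 0.128 FPKM, and the repressor IRF2BP2, at 39.8 ± 1.94 against 161 ± 10.1 FPKM. So were HIST1H3D, at 0.838 ± 1.41 against 4.57 ± 0.716 FPKM, the mTOR inhibitor DDIT4, at 16.8 ± 7.61 against 64.4 ± 35.3 FPKM, and the peptide hormone gene ADM, at 4.75 ± 3.74 against 18.55 ± 11.2 FPKM.

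Camera called 6 lists between the compounds, and none held with an estimated correlation. Haematopoietic transcription factors were lower with ARV-825, 21 of 28 down and 2 up, the same adjusted over the list alone (median -0.53, adjusted p = 8.74e-06, and adjusted p = 0.0615 with an estimated correlation). GFI1 stood at 18.4 ± 0.684 against 54.1 ± 1.31 FPKM, and NFE2 differed by -1.53. Cholesterol synthesis genes were higher, 21 of 24 up and 1 down, or 22 and 1 adjusted over the list alone (median 0.36, adjusted p = 5.58e-07, and adjusted p = 0.0615 with an estimated correlation). Among them were IDI1 (0.74) and HMGCS1 (0.69). Targets of p53 were higher, 15 of 25 up and 0 down, the same adjusted over the list alone (median 0.20, adjusted p = 0.000135, and adjusted p = 0.189 with an estimated correlation), with MDM2 at 0.95 and PMAIP1 at 1.20. Monocyte and macrophage genes were higher, 15 of 23 up and 4 down, or 16 and 4 adjusted over the list alone (median 0.51, adjusted p = 0.000821, and adjusted p = 0.0615 with an estimated correlation). CYBB, a subunit of the phagocyte oxidase, stood at 0.87, against CCR2 at -1.10 and CD180 at -0.97. Neutrophil granule genes were higher, 8 of 10 up and 0 down, the same adjusted over the list alone (median 0.52, adjusted p = 0.000821, and adjusted p = 0.238 with an estimated correlation), including AZU1 (1.02), PRG2 (0.81) and RNASE3 (0.67). Immediate early genes were lower, 17 of 24 down and 1 up, the same adjusted over the list alone (median -0.36, adjusted p = 0.000821, and adjusted p = 0.162 with an estimated correlation), including the phosphatase DUSP6 (-1.23) and FOSL2 (-1.06). The other 20 lists were not called (adjusted p = 0.119 to 0.955), among them histone genes, 5 up and 7 down of 35, or 5 and 6 adjusted over the list alone (median 0, adjusted p = 0.955). MYC-associated genes had 14 up and 8 down of 40, or 13 and 7 adjusted over the list alone (median 0.06, adjusted p = 0.24). Anti-apoptotic genes, with 0 up and 4 down of 7 (median -0.34, adjusted p = 0.119), passed without a filter on low values (adjusted p = 0.0157). Members of these lists that differed included PIM1, at 48.1 ± 1.17 FPKM with ARV-825 and 152 ± 2.01 FPKM with OTX015, CXCL8 (-1.42), TRIB3 (-1.12), HSPA8 (-0.88), BCL2A1 (-0.90) and ZNF692 (1.21). Standard errors of the log2 differences named here ran from 0.041 to 0.415.

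Set side by side, the effects of the drugs on 10819 genes were related, with 2868 genes that rose with both and 2856 that fell with both, where independent lists would share 1395 and 1393. Of these 5724 genes, 2007 moved further with ARV-825, 1026 moved further with OTX015, and for 2691 no difference was detected. In the opposite direction were 412 genes, whose difference between the compounds passed the threshold as their opposite calls entail. Of these, 158 rose with ARV-825 and fell with OTX015, and 254 did the reverse. PMAIP1 (NOXA) was at 10.9 FPKM in control, 9.32 with OTX015 and 22.7 with ARV-825, and the MAP kinase phosphatase DUSP6 at 34.3, 55.0 and 22.9 FPKM. CD69 was at 3.49, 6.18 and 0.755 FPKM. Across genes, which are not independent replicates, the log2 changes correlated with Pearson r = 0.815 and Spearman rho = 0.787, and had the same sign in 79.3% of genes. Both comparisons used the same control libraries, and 100 simulations of unchanged groups against them gave a same-sign share of 66.7%. Without mitochondrially encoded genes, r was 0.824 and the covariance 0.347, against a mean r of 0.5 and a mean covariance of 0.00455 in the simulations without these genes. The simulations share these controls too. Their covariance of 0.00455 against 0.347 argues against the spread of the control libraries as the main source of the relation. Shared calls were set beside independent lists, so part of their excess can come from the shared controls. With 3 control libraries the controls cannot be split into parts of at least 2, so a deviation common to all 3 cannot be excluded.

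**Figure D3:**
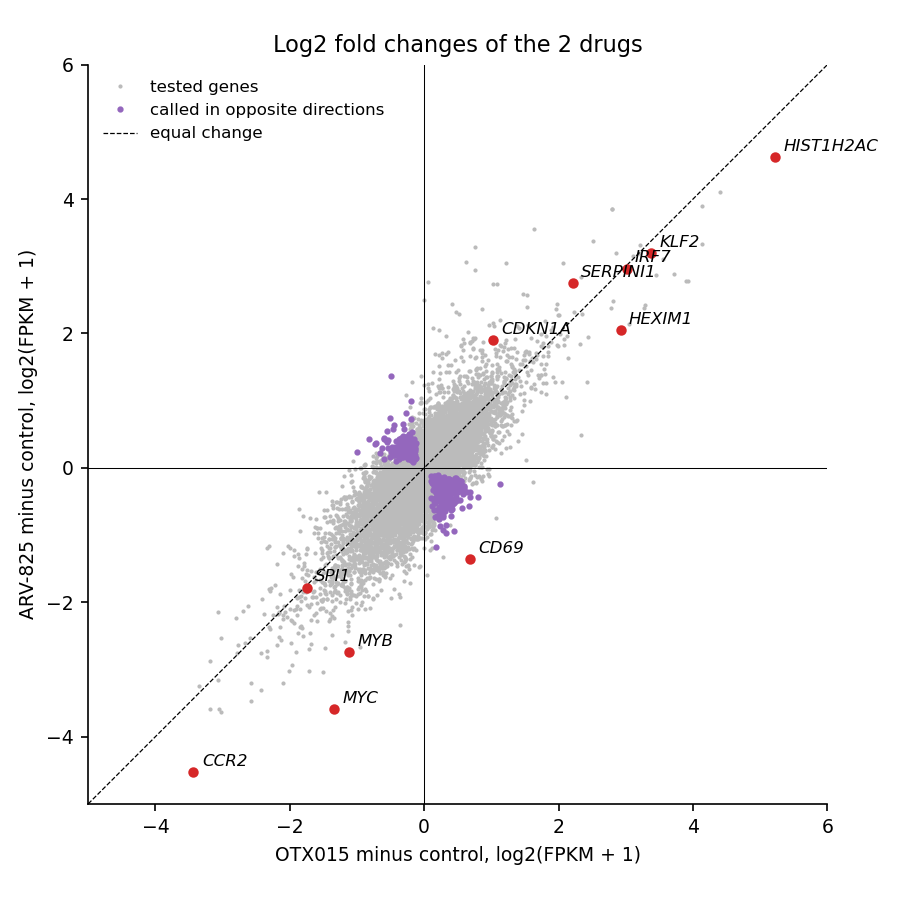
Log2 change with ARV-825 against log2 change with OTX015, both versus control, for each tested gene other than mitochondrially encoded genes, with purple points for the 412 genes called in opposite directions and a dashed line of equal change. MYC lies at -1.34 with OTX015 and -3.59 with ARV-825, and SPI1 lies near the line at -1.75 and -1.78.

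In the shRNA libraries, RUNX1 stood at 69.8, 72.2 and 69.8 FPKM with non-targeting shRNA and at 37.2, 42.9 and 36.0 FPKM with RUNX1 shRNA. Its mean fell from 70.6 ± 1.4 to 38.7 ± 3.65 FPKM (n = 3 libraries per group, adjusted p = 3.71e-05). Sample titles of the knockdown group name Runx3 while their treatment label names RUNX1. RUNX3 stood at 27.5, 28.5 and 25.02 FPKM with non-targeting shRNA and at 28.0, 27.9 and 29.3 FPKM with RUNX1 shRNA (log2 change 0.07, 95% interval -0.047 to 0.186, adjusted p = 0.341). VIM, the intermediate filament vimentin, fell from 164 ± 0.719 to 65.1 ± 0.739 FPKM, while CD34, a marker of immature blood cells, rose from 15.3 ± 0.559 to 29.8 ± 0.63 FPKM. Limma called 2988 of 10925 genes (27.4%), of which 1476 rose (49.4%, or 54.6% of 2980 after median-ratio rescaling) and 1512 fell, with 50 up and 18 down by at least 2-fold. The groups were fully apart in 44.1% of genes, against 10% by chance, and the median absolute log2 change of called genes was 0.26.

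MYC fell from 262 ± 2.92 to 211.5 ± 4 FPKM with RUNX1 shRNA (adjusted p = 8.12e-05), BCL2 from 29.7 ± 1.43 to 20.6 ± 1.21 FPKM (log2 change -0.51, adjusted p = 0.000349), and SPI1 from 159 ± 1.89 to 143 ± 6.19 FPKM (-0.16, adjusted p = 0.00985). CDKN1B rose by 0.35 ± 0.07, BCL2L1 by 0.27 ± 0.039, CDKN1A by 0.21 ± 0.024, CBFB by 0.20 ± 0.043 and MCL1 by 0.14 ± 0.031. CEBPA changed by -0.17 (adjusted p = 0.0155), a call lost without non-targeting replicate 2 (adjusted p = 0.0588) or 3 (0.0531). BCL2L11 changed by -0.21 (adjusted p = 0.0348), a call lost without a filter on low values (adjusted p = 0.0561), after median-ratio rescaling (0.0519) and without any of non-targeting replicates 1, 2 and 3 or RUNX1 shRNA replicates 1 and 3 (0.065 to 0.119). Not past the threshold were MYB (-0.08, adjusted p = 0.0707), HEXIM1 (0.11, adjusted p = 0.119), BRD2 (0.08, adjusted p = 0.111), CRBN (-0.06, adjusted p = 0.464), CDK6 (0.04, adjusted p = 0.7) and BRD3 (0.11, adjusted p = 0.353). BRD3 passed without non-targeting replicate 3 (0.21, adjusted p = 0.0254). SERPINI1, with a mean of 0.372 and 0.416 FPKM, was below the level tested.

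The largest rises with RUNX1 shRNA were again histone genes, with large spread between libraries. HIST1H4H rose from 1.72 ± 0.745 to 16.8 ± 9.77 FPKM (adjusted p = 0.00233), HIST2H2BF from 1.83 ± 0.699 to 13.7 ± 7.13 FPKM and HIST1H1E from 1.87 ± 0.268 to 14.05 ± 7.57 FPKM. HIST2H2BE rose from 4.01 ± 1.04 to 22.4 ± 10.5 FPKM, HIST1H2BD from 1.88 ± 0.775 to 11.9 ± 4.85 FPKM and HIST1H4A from 0.856 ± 0.232 to 6.76 ± 3.18 FPKM. The largest falls were those of the thioesterase LYPLA1, from 86.6 ± 2.52 to 33.8 ± 2.38 FPKM (-1.33), VIM (-1.32, adjusted p = 4.22e-08) and STARD3NL, from 35.6 ± 1.59 to 14.01 ± 0.654 FPKM. They were followed by the sialic acid enzyme CMAS, from 20.7 ± 1.24 to 8.001 ± 1.12 FPKM, the neutrophil protease CTSG, from 11.9 ± 0.658 to 4.52 ± 0.376 FPKM, and the glycosylation subunit OSTC, from 57.8 ± 0.776 to 24.4 ± 0.964 FPKM. LYPLA1, VIM, STARD3NL, CMAS and OSTC hold the 7-mer GCAAGAT in an annotated 3' UTR and CTSG does not. It was present in 19 of the 31 genes that fell by at least as much as RUNX1 (RUNX1, which lacks it there, is 1 of the 31), against 8.49% of all tested genes with an annotated 3' UTR. Histone FPKM summed over the list were 214, 322 and 121 in the RUNX1 shRNA libraries, against a mean of 54.1 ± 9.17 with non-targeting shRNA.

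**Figure D4:**
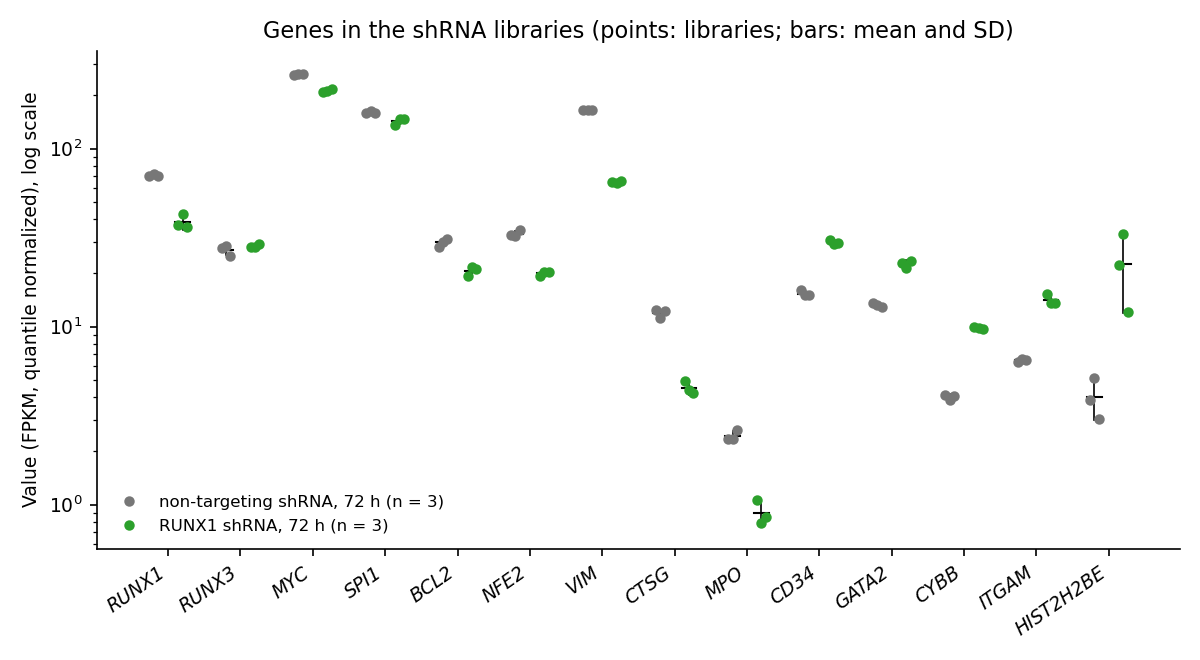
FPKM of 14 genes on a log axis with non-targeting and RUNX1 shRNA, with points for the 3 libraries of a group and bars for the mean and SD. RUNX1 fell from 70.6 to 38.7 FPKM while RUNX3 stood at 27.0 and 28.4 FPKM, and the RUNX1 shRNA libraries of HIST2H2BE are spread around a mean of 22.4 ± 10.5 FPKM.

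Camera called 9 of 26 lists with RUNX1 shRNA, and none held with an estimated correlation. For G1/S genes and stem and progenitor genes the estimated correlations were -0.013 and -0.048, below the preset 0.01. The loss of those calls therefore cannot be put down to members that move together. Histone genes rose, 27 of 27 up, the same adjusted over the list alone (median 1.35, adjusted p = 5.92e-13, and adjusted p = 0.616 with an estimated correlation). Neutrophil granule genes fell, 7 of 8 down and 1 up, the same adjusted over the list alone (median -0.53, adjusted p = 0.000791, and adjusted p = 0.448 with an estimated correlation). They included CTSG, the peroxidase MPO, from 2.44 ± 0.168 to 0.9025 ± 0.144 FPKM, and CFD, from 19.1 ± 2.11 to 10.7 ± 0.273 FPKM. Cholesterol synthesis genes fell, 12 of 24 down and 1 up, or 13 and 1 adjusted over the list alone (median -0.13, adjusted p = 0.000791, and adjusted p = 0.448 with an estimated correlation), including HMGCS1 (-0.59) and DHCR7 (-0.46). Targets of p53 rose, 9 of 25 up and 2 down, or 13 and 3 adjusted over the list alone (median 0.12, adjusted p = 0.0182, and adjusted p = 0.638 with an estimated correlation), including BTG2 (0.57) and GADD45A (0.34). G1/S genes fell, 8 of 30 down and 0 up, the same adjusted over the list alone (median -0.08, adjusted p = 0.0251, and adjusted p = 0.448 with an estimated correlation), including the replication factors CDC45 (-0.20) and RFC2 (-0.20). Mitochondrially encoded genes fell, 6 of 13 down and 0 up, or 9 and 0 adjusted over the list alone (median -0.24, adjusted p = 0.00663, and adjusted p = 0.616 with an estimated correlation). Without a filter on low values the calls of MT-ATP6 (limma adjusted p = 0.133), MT-ND4L (0.124) and MT-ND2 (0.0806) were lost. Exact values of these abundant genes recur, with MT-ATP8 at 35700 FPKM in libraries of both groups, so their changes can be steps in rank.

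Weaker calls were those of stem and progenitor, heat shock and ribosomal protein genes. Stem and progenitor genes rose, 5 of 8 up and 2 down, or 6 and 2 adjusted over the list alone (median 0.48, adjusted p = 0.0489, and adjusted p = 0.448 with an estimated correlation), with CD34 (0.91), GATA2 (0.73) and the receptor kinase FLT3 (-0.59). Heat shock genes fell, 6 of 19 down and 1 up, the same adjusted over the list alone (median -0.07, adjusted p = 0.0489, and adjusted p = 0.638 with an estimated correlation), including CHORDC1 (-0.53). Ribosomal protein genes were called upward relative to other genes, with 3 of 44 up and 0 down, or 1 and 0 adjusted over the list alone (median 0.03, adjusted p = 0.0424, and adjusted p = 0.698 with an estimated correlation), including RPSA (0.16), and fry did not call them (adjusted p = 0.157). The stem call was lost with a pseudocount of 5 (adjusted p = 0.0522), without a filter (0.179), with a mean of at least 5 FPKM (0.214), after median-ratio rescaling (0.0792) and without non-targeting replicate 2 (0.0785) or RUNX1 shRNA replicates 2 (0.0742) or 3 (0.0606). Ribosomal genes lost theirs at a mean of at least 5 FPKM (0.0775) and without non-targeting replicate 1 (0.137) or RUNX1 shRNA replicate 1 (0.231). Heat shock genes lost theirs with a pseudocount of 5 (0.0522), without a filter (0.0562), at a mean of at least 5 FPKM (0.105), after median-ratio rescaling (0.0753) and without non-targeting replicate 1 (0.0907) or 2 (0.0872) or RUNX1 shRNA replicate 2 (0.081) or 3 (0.0807). Without genes holding the 7-mer GCAAGAT, none of the 3 calls held (adjusted p = 0.284 for stem and progenitor, 0.186 for heat shock and 0.0815 for ribosomal protein genes).

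The other 17 lists were not called with RUNX1 shRNA (adjusted p = 0.205 to 0.955), though GM-CSF and STAT5 response genes passed at a mean of at least 5 FPKM (adjusted p = 0.0466). Monocyte and macrophage genes had 6 up and 6 down of 21, or 9 and 8 adjusted over the list alone (median 0.01, adjusted p = 0.565). CYBB rose from 4.03 ± 0.138 to 9.825 ± 0.135 FPKM, the integrin ITGAM from 6.48 ± 0.121 to 14.1 ± 0.984 FPKM and FCGR1A from 28.9 ± 2.28 to 51.3 ± 4.26 FPKM. Haematopoietic transcription factors had 8 up and 7 down of 26, or 8 and 8 adjusted over the list alone (median 0.07, adjusted p = 0.565), with NFE2 down from 33.3 ± 1.27 to 19.9 ± 0.647 FPKM. Reported RUNX1 target genes had 7 up and 6 down of 17, or 8 and 7 adjusted over the list alone (median -0.01, adjusted p = 0.936, test direction up), among them the cyclin gene CCND2, up from 31.0 ± 0.473 to 59.7 ± 10.7 FPKM. MYC-associated genes had 4 up and 12 down of 40, the same adjusted over the list alone (median -0.05, adjusted p = 0.205), including TMEM97 (-0.36). Elsewhere the glucose transporter SLC2A1 fell from 41.1 ± 1.22 to 20.7 ± 2.31 FPKM, the asparagine synthetase ASNS rose by 0.71 and the chaperone CALR changed by -0.49. Standard errors of the log2 changes named for RUNX1 shRNA ran from 0.024 to 0.401.

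Whether genes that moved with RUNX1 shRNA moved with the drugs was tested with the called genes as sets. Of 1465 genes that fell with RUNX1 shRNA and were tested in the drug libraries, 700 fell and 427 rose with ARV-825, where independent lists would give 574 and 512 (median -0.14, camera adjusted p = 0.0311 over 4 tests, and adjusted p = 0.0642 without ARV-825 replicate 2). With OTX015, 727 of them fell and 366 rose, against 500 and 519 (median -0.16, adjusted p = 0.000234). Neither held with an estimated correlation (adjusted p = 0.814). Of the fallen genes with an annotated 3' UTR, 17.3% hold the 7-mer GCAAGAT, against 8.49% of all such genes. Part of the fallen set may therefore not follow from less RUNX1. Of 1440 genes that rose with RUNX1 shRNA, 541 rose and 554 fell with ARV-825, against 503 and 564 (median 0.02, adjusted p = 0.891). With OTX015, 614 rose and 461 fell, against 511 and 492 (median 0.11, adjusted p = 0.333). With sets limited to changes of at least 2-fold, the risen genes passed with ARV-825 (adjusted p = 3.73e-05) and OTX015 (adjusted p = 0.000894). The fallen genes then passed with OTX015 (adjusted p = 0.0274) and not with ARV-825 (adjusted p = 0.401). Of the 50 genes that rose at least 2-fold, 39 are histone genes, and without these the risen genes gave adjusted p = 0.571 with ARV-825 and 0.356 with OTX015. The call of the fallen genes with OTX015 was then lost too (adjusted p = 0.0822), although they include 0 histone genes, because the adjustment runs over the 4 tests together. Across the 10573 genes of both tables, log2 changes with RUNX1 shRNA correlated with those of ARV-825 at Pearson r = 0.146 (Spearman rho = 0.088) and of OTX015 at r = 0.196 (rho = 0.155).

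Among genes that moved the same way with RUNX1 shRNA and ARV-825, the largest shared falls were in TTC27 (log2 changes -1.13 and -1.23), the GTPase RHOU (-1.10 and -1.86), the oxysterol receptor GPR183 (-0.84 and -2.28), the sphingosine receptor S1PR3 (-0.80 and -1.12) and the sialyltransferase ST3GAL4 (-0.80 and -1.16). The largest shared rises were in the histone genes HIST2H2BE (2.14 and 2.38), HIST1H2BD (2.12 and 3.31), HIST2H2BF (2.28 and 1.94), HIST1H2AE (1.97 and 1.89) and HIST1H2BO (1.88 and 3.20). With RUNX1 shRNA, the calls of HIST1H2AE (adjusted p = 0.0684) and HIST1H2BO (0.112) were lost without a filter on low values. That of HIST1H2BO was also lost with limma without the trend (0.0571). It was lost too without any of non-targeting replicates 1, 2 and 3 or RUNX1 shRNA replicates 1 and 2 (0.0614 to 0.088). TTC27 and RHOU hold the 7-mer GCAAGAT in an annotated 3' UTR.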

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

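The tests in this part were set before their results were seen, except that the genes named were chosen after their values were seen. ARV-825 and OTX015 moved 412 genes in opposite directions against the same control. The test of the difference between the drugs passed the threshold for each, which their selection by opposite calls entails. The 158 genes that rose with ARV-825 and fell with OTX015 had median log2 changes of 0.3 and -0.28, and the 254 that fell with ARV-825 and rose with OTX015 had medians of -0.31 and 0.28. On the first side were BZRAP1, which encodes a protein that binds the peripheral benzodiazepine receptor (9.86 FPKM in control, 6.77 with OTX015 and 27.0 with ARV-825), the purinergic receptor gene P2RY11 (8.98, 5.80 and 13.6), the homeobox gene HOXB3 (6.63, 4.03 and 9.27), the calprotectin subunit S100A8 (3.41, 2.27 and 4.77) and the pro-apoptotic PMAIP1 (10.9, 9.32 and 22.7). On the other side were PHF3 (19.0, 28.7 and 12.3), the cytokine OSM (1.31, 3.03 and 0.708), the transcription factor FOXO1 (3.79, 5.35 and 2.13), the BH3-only gene BMF (9.27, 11.4 and 5.17) and the interferon signalling factor IRF9 (10.2, 15.8 and 8.21).

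A loss of RNA per cell after ARV-825, hidden by quantile normalization, would push genes only towards a rise with ARV-825. The 254 genes on the other side argue against a loss after ARV-825 for that side. They do not bear on such a loss after OTX015, which would push genes towards a rise with OTX015 and was not tested. For the 158 genes that rose with ARV-825, a loss after ARV-825 stays open, because no reliable value here sets its size. The planned gauge was the change of mitochondrially encoded genes, with a median log2 change of 0.09 after ARV-825. As 6 of them were listed at 0 in ARV-825 replicate 1, that median is uncertain, and a shift of its size was not tested. The 7.59% of the 158 genes left above 0 by a log2 shift of 0.5 decides nothing, since that shift exceeds their median rise of 0.3. The values of 0 for 6 mitochondrially encoded genes in ARV-825 replicate 1 are argued against as the source of the pattern, since 369 opposite genes were called without that library. Degradation of BET proteins in place of inhibition is a biological explanation that the design names and that stays untested. For the 158 genes it cannot be told apart from a hidden loss of RNA after ARV-825. For the 254 genes it cannot be told apart from a hidden loss of RNA after OTX015.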

How the results depend on the processing

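Among the tests here, fry and the removal of histone genes for the RUNX1 sets, quantile normalization repeated without mitochondrially encoded genes, and removal of genes with the 7-mer were chosen after the data were seen. Of 416 results for named genes, 378 kept their direction and side of the threshold under each setting that tested them, 28 lost the threshold and 10 gained it under at least 1 setting, and 0 reversed. At a mean of at least 5 FPKM 348 of the 416 were tested, and the settings without mitochondrially encoded genes or without the 7-mer covered the drug and the shRNA results alone. Counts of changed genes stayed within 1.5 times under pseudocount, filter, median-ratio, trend and 2-group settings. Leaving out 1 library gave 7492 to 8102 for ARV-825, 6895 to 7689 for OTX015, 5573 to 6267 between the drugs, and 1997 (without non-targeting replicate 3) to 2840 for RUNX1 shRNA, the lowest close to 1.5 times below 2988, and fewer samples per fit is part of this setting. Without a filter 2454 genes were called for RUNX1 shRNA, of which 2216 were among the 2988. An added threshold of 1 on the absolute log2 change left 1359, 862, 205 and 68 genes in the 4 comparisons, of which 35%, 37.7%, 44.4% and 73.5% rose. Median-ratio rescaling moved the median of all genes by at most 0.046, yet it turned the majority direction among called genes, with the share that rose going from 48.2% to 52.5% with ARV-825, from 42.5% to 50.8% between the drugs and from 49.4% to 54.6% with RUNX1 shRNA. With OTX015 the share went from 51.8% to 48.3% without a filter. Opposite genes numbered 275 to 439 with 1 library left out.

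The correlation of the drugs' log2 changes, 0.815, was 0.806 with a pseudocount of 0.1, 0.823 with 5, 0.831 at a mean of at least 5 FPKM, 0.828 after normalization without mitochondrially encoded genes, and 0.795 (without ARV-825 replicate 2) to 0.824 (without ARV-825 replicate 1). Lists called with an estimated correlation were 0 for ARV-825, 1 for OTX015, 0 between the drugs and 0 for RUNX1 shRNA, and with fry, which asks another question, 18, 19, 15 and 13. A call lost with an estimated correlation does not by itself show correlated members. The estimate was -0.013 for G1/S genes with RUNX1 shRNA, whose call was lost. Camera with an estimated correlation also rests on the few degrees of freedom of the libraries, which raises p by itself. Fry turned the direction of reported RUNX1 targets between the drugs (adjusted p = 0.00419) and of the genes risen with RUNX1 shRNA in ARV-825 (adjusted p = 0.0093), and the cause was not tested. For the genes fallen with RUNX1 shRNA, camera with an estimated correlation gave adjusted p = 0.814 in ARV-825 and in OTX015. With 1 library left out their adjusted p ran from 0.0145 to 0.0642 in ARV-825, the highest without ARV-825 replicate 2 and the sole value past 0.05, and from 5.56e-05 to 0.000545 in OTX015. With sets limited to 2-fold changes, risen genes gave adjusted p = 3.73e-05 in ARV-825 and adjusted p = 0.000894 in OTX015 and fallen genes adjusted p = 0.401 in ARV-825, with fewer genes per set. Without the 39 histone genes among the 50 risen genes, these gave adjusted p = 0.571 and adjusted p = 0.356. The fallen genes, which include 0 histone genes, gave adjusted p = 0.535 in ARV-825 and adjusted p = 0.0822 in OTX015, moved only by the adjustment over the 4 tests. Without genes holding the 7-mer, 2630 genes were called for RUNX1 shRNA, each among the 2988, and 3 list calls were lost, those of ribosomal (adjusted p = 0.0815), stem (0.284) and heat shock genes (0.186).

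Replicate numbers did not pair the samples: correlations of same-numbered deviations were -0.44 to 0.07 in the drug table and -0.01 to 0.06 in the shRNA table, and 0 of 9 and 4 of 6 libraries correlated best with their own number. The highest correlation was between OTX015 replicate 3 and ARV-825 replicate 2, at 0.53. With the number as a replicate block, 7771, 7262, 5884 and 2585 genes were called. Then 6 results for named genes and 1 list, each with RUNX1 shRNA, were no longer past the threshold. Among the genes was BCL2L11 (limma adjusted p = 0.0737), and the list was heat shock genes (camera adjusted p = 0.0545). Unknown depth limits what can be said of genes near 1 FPKM.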

Other observations

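Among the tests in this part, those of G1/S genes beside the histone rise were set after the result was seen. Some changes were in markers of other blood and tissue types and in genes not named so far. With ARV-825, TFRC, which takes up iron, fell by 0.54 on the log2 scale, from 42.6 ± 2.88 to 28.9 ± 1.38 FPKM (n = 3 libraries per group, adjusted p = 3.16e-05), while the platelet receptor subunit GP1BA rose from 0.512 ± 0.0478 to 1.87 ± 0.174 FPKM, NRGN from 22.9 ± 2.95 to 34.5 ± 1.34 FPKM, the adhesion molecule NCAM1 from 11.85 ± 0.812 to 19.6 ± 2.6 FPKM and the matrix gene FBN1 from 0.5025 ± 0.0539 to 1.83 ± 0.138 FPKM. With OTX015, TFRC fell to 26.35 ± 2.32 FPKM and NRGN rose to 37.2 ± 2.13 FPKM. The cereblon neosubstrate gene GSPT1 and the ligase scaffold gene CUL4A fell by 0.54 and 0.78 on the log2 scale with ARV-825, and by 0.54 and 0.64 with OTX015. The proteasome subunits PSMD11 (-0.60), PSMC2 (-0.56) and PSMC1 (-0.51) fell with ARV-825. In the shRNA libraries the cyclin CCND3 (-0.49) and the interleukin-2 receptor chain IL2RA (-0.70) fell, while the reticulum quality control gene EDEM1 (0.52) and the chemokine CCL5 (0.58) rose.

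In the RUNX1 shRNA comparison a single 7-mer, GCAAGAT, marked the genes that fell. Over 915 genes that hold it in an annotated 3' UTR, log2 changes were shifted by -0.15 (regression t = -18.9, the lowest of any 7-mer, with genes as units), followed by the overlapping CAAGATA (t = -11.1), TGCAAGA (t = -10.7) and AGCAAGA (t = -10.6), whereas the lowest values in the drug comparisons with control were -4.9 and -5.0. It was held by 17.3% of fallen, 5.61% of risen and 7.35% of other genes, and by 61.3% of the 31 genes that fell as far as RUNX1, among them VIM, LYPLA1, GNB1, EIF2S2, ATP5C1, TMSB10 and SLC2A1. These values are consistent with a hairpin that represses transcripts through a seed match, and part of the fallen set may therefore not follow from less RUNX1. The hairpin sequence was not used here, and 7 of 9 protein-coding RUNX1 transcripts hold the 7-mer, which a random sequence as long as the longest of them would do with a chance of 35.8%. The longest annotated 3' UTR of RUNX1 does not hold it, and RUNX1, itself 1 of the 31 genes, is counted as without it, as are CTSG, MS4A3, CST7 and BZRAP1.

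Histone genes rose with both drugs and with RUNX1 shRNA in camera at a preset correlation, and not with an estimated correlation (adjusted p = 0.704 with ARV-825, adjusted p = 0.614 with OTX015 and adjusted p = 0.616 with RUNX1 shRNA). Their summed FPKM was 148 ± 10.8 in control, 1130 ± 271 with ARV-825 and 1490 ± 322 with OTX015, and 54.1 ± 9.17 with non-targeting against 219 ± 101 with RUNX1 shRNA. ARV-825 replicate 2, at 1444, and OTX015 replicate 3, at 1849, stood above the other libraries of their groups, which reached 975.7 and 1369.

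Reads moved between near-identical copies within the histone list would leave its sum in place. The lowest treated library lay at least 1.88 times above the highest control library in the 3 comparisons, which argues against that within the list. Copies outside the list, such as HIST2H4B and HIST2H2AA4, are not in the sum, so reads moved from them were not tested. Leaving out any 1 library left a list median of at least 1.2, which argues against a single library as the source. More cells in S phase would raise G1/S genes too. With RUNX1 shRNA 0 of 30 G1/S genes rose and 8 fell (upper 95% bootstrap bound of the median -0.05, genes taken as independent). The rule for RUNX1 shRNA was set after these values were seen and differs from that for the drugs, so passing it adds no support. As a description, the values argue against more cells in S phase with RUNX1 shRNA. With the drugs G1/S genes went both ways, so that an upper bound of 0.167 of the histone median decides nothing and S phase stays open. As most histone messages end without a poly(A) tail, more tailed histone transcripts or a difference in RNA selection between libraries may contribute to a rise of at least 1.88 times, and neither was tested.

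A fall of longer genes after ARV-825, as a block of elongation might give, was not seen. Spearman rho between gene span and log2 change across genes was 0.006 with ARV-825, 0.033 with OTX015 and 0.158 with RUNX1 shRNA.

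The 6 libraries of each comparison can be split into 3 and 3 in 10 ways, too few for a share under 0.05. With the libraries of the compared groups alone, the real split called 7923 genes for ARV-825 (8168 at an unadjusted p under 0.05), 7824 for OTX015 (8035), 5842 between the drugs (6411) and 2988 for RUNX1 shRNA (4371) with limma. In each comparison 1 of the 10 splits, the real one, called as many. The highest other split called 0 genes in each, with 59, 39, 281 and 353 genes at an unadjusted p under 0.05. Each other split mixes libraries of both groups, so a difference between the groups enters its spread and lowers its count. The low counts of the other splits therefore decide nothing about chance.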
